A study of Mus musculus with 6 samples.

How the data were processed

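The series holds 6 RNA sequencing libraries from BMDM of 8-week-old wild-type C57BL/6 mice, 3 per group. Per the labels' protocols, marrow cells were grown for 7 days in 20 ng/ml M-CSF, then kept in M-CSF with or without 10 ng/ml IL-4 for 4 h. Polyadenylated RNA was selected from 100 ng of total RNA, per the labels' protocols. Groups and replicate numbers were taken from the sample titles and matched to the column names.

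Per the submitters' processing notes, bcl2fastq, STAR, HOMER 4.11.1 and DESeq2 were used with the mm10 build, without stated settings. Per the file headers, HOMER counted reads in exons of RefSeq genes with 1 transcript kept per gene. The authors deposited a table of TPM per library and gene. The authors' deposited table of the comparison holds per-library values on a log2 scale, a log2 fold change, a p-value and an adjusted p-value, per the file headers. The header does not name the transformation behind the log2 values, and the sign of the fold change was checked against the library means (M2 minus M0). Each table has 25124 genes, and 3 entries shifted by commas in the annotation were realigned. The TPM of the deposited genes sum to 548160 to 553186 in M0 libraries and 542749 to 543854 in M2 libraries, short of a full TPM total. Reads recovered in these genes make up 89.8% to 90.9% of the tag totals in the file headers, and the cause of the shortfall was not tested.

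TPM multiplied by transcript length gave multiples of a fixed step in each library. By these, 99.8% to 99.9% of nonzero values were whole numbers of reads within 0.1 read, and reads per gene could be recovered. The recovered totals were 16913185 to 19019896 reads per library. Intervals and floors from these reads cover counting error only, at a confidence level of 95%, and a group with no read was set to a floor of 3 reads over the group. No read was found for 6612 genes, and 414 genes had more than 1 copy in the annotation, 20 of them tested. Of 261 tested genes with a transcript under 200 bases, 47 passed, and their values are uncertain. Scatter between libraries was summarised as a chi-square per degree of freedom on recovered reads.

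Since the deposited unit is TPM, the test was limma-trend (limma 3.58.1, R 4.3.3; trend and robust moderation, two-sided) on log2 of TPM with a pseudocount of 1, for genes with a TPM of at least 1 in at least 3 libraries. Group was the only term. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and larger changes were those with an absolute log2 fold change of at least 1. Median scaling divided each library by its median-ratio factor, from 0.941 to 1.09, after which the test was repeated. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Coordinates are those of the deposited tables in mm10, and exon numbers are those of GENCODE M21 transcripts matched by RefSeq identifier.

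Before the data were examined, 31 gene lists of 649 genes were fixed, all of which were found in the tables, 1 through an older symbol. The lists covered IL-4 response and alternative activation, JAK-STAT components and feedback, classical activation, type I interferon response and Toll-like receptors. They also covered chemokine receptors and motility, MHC class II and antigen presentation, phagocytosis and efferocytosis, cholesterol synthesis, LXR targets and fatty acid oxidation. Others held glycolysis, oxidative phosphorylation, arginine and polyamine metabolism, ribosome biogenesis, cell cycle, circadian clock and immediate early genes. The rest were integrated stress and unfolded protein response, extracellular matrix, macrophage identity, heat shock, hypoxia and 8 other cell types. Lists with at least 3 tested members, 26 in all, were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists. Members were also adjusted over the list alone. Another 5 lists were written after gene values had been seen. Named genes were fixed by rule before the data were examined. The rule took the 10 largest rises and 10 largest falls with a mean TPM of at least 1 in the higher group and no overlap between groups, up to 4 members per list with the largest change among those past the threshold, and a set of markers named whatever their result.

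The alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter, a minimum of 50 recovered reads in 3 libraries, replicate number as a block, each library left out in turn, camera with an estimated correlation, fry, and lists without shared genes. Those added after seeing the data were median-scaled TPM, limma-voom on recovered reads, limma-trend on the authors' deposited log2-scale values, removal of a trend on transcript length (loess span 0.5), and a test against a fold change of 1.5. Planned tests on raw counts were not run because the deposited unit was TPM.

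The test was tried on simulated data, with negative-binomial reads for the real genes drawn from their mean shares, library totals and within-group spread, and 200 genes changed up or down in M2 against M0. Among 11171 tested genes it recovered 89.6% of 67 genes changed 1.5-fold, 97.0% of 67 changed 2-fold and all 65 changed 4-fold. In 30 further draws, unchanged genes made up 6.58% of the calls on average (4.06% to 9.62%), above the 5% aimed for. After median scaling they made up 6.59%. TPM were scaled by the simulated reads and changes were at most 4-fold, so unchanged genes hardly shifted (median log2 fold change -0.0104 in the draw above). The real median gene shifted by -0.152, with 7071 genes passing. The draws therefore cannot give the share of false calls of the unscaled test on the real values. The simulation was run after the first fit to the real values, and the fit was not altered. With 1 list moved 1.5-fold, camera called that list and none of the others, but simulated genes vary independently, which real genes do not.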

Results

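Messenger RNA was profiled in bone marrow-derived macrophages (BMDM), cells grown from mouse marrow with macrophage colony-stimulating factor (M-CSF). The 6 libraries fell into 2 groups of 3. M0 cells were kept in 20 ng/ml M-CSF alone. M2 cells were given 10 ng/ml interleukin-4 (IL-4), the cytokine that drives alternative macrophage activation, together with the M-CSF. RNA was taken 4 h later, after 7 days of culture. The deposited TPM values (transcript abundances scaled for length and depth) corresponded to 16913185 to 19019896 reads in genes per library, 89.8% to 90.9% of the tag totals in the file headers. Between 10968 and 11131 genes reached 1 TPM in a library, and 1 read in a 1-kb transcript gave 0.0610 to 0.0700 TPM. Scatter between M2 replicates was close to counting error, with a chi-square per degree of freedom of 1.54 to 1.73. M0 replicates 1 and 3 gave 2.31, whereas M0 replicate 2 gave 9.52 and 10.7 against the other two. Pairs of libraries from different groups gave 119 to 146.

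The only comparison of the series, M2 against M0, asks which transcripts differ after 4 h of IL-4. Retnla, Chil3 and Arg1, markers of alternative activation, rose most among the IL-4 response genes on the fitted scale. Retnla, which encodes a resistin-like secreted protein, had 0.172 ± 0.2004 TPM in M0 and 4859 ± 135 TPM in M2 (SD, n = 3 each). Chil3, which encodes a chitinase-like lectin, went from 3.61 ± 0.128 to 2900 ± 65.5 TPM, and Arg1, the arginase that turns arginine into ornithine, from 1.55 ± 0.328 to 1009 ± 7.40 TPM. Transcripts of the interferon-induced Ifit family fell, with Ifit3 at 77.5 ± 7.88 TPM in M0 and 2.61 ± 0.563 TPM in M2. Of the cell cycle genes 34 of 34 fell, and of the ribosome biogenesis genes 35 of 36 fell. Of the tested MHC class II and antigen presentation genes, 10 of 16 rose, 1 fell and 5 did not pass. The calls of these 3 lists were lost with an estimated correlation (adjusted p = 0.268, 0.135 and 0.268 with an estimated correlation). The correlations estimated for them were 0.268, 0.0189 and 0.288, against the preset 0.01. That setting also tests on fewer degrees of freedom, so that a call lost there need not be due to correlation between genes.

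**Figure D1:**
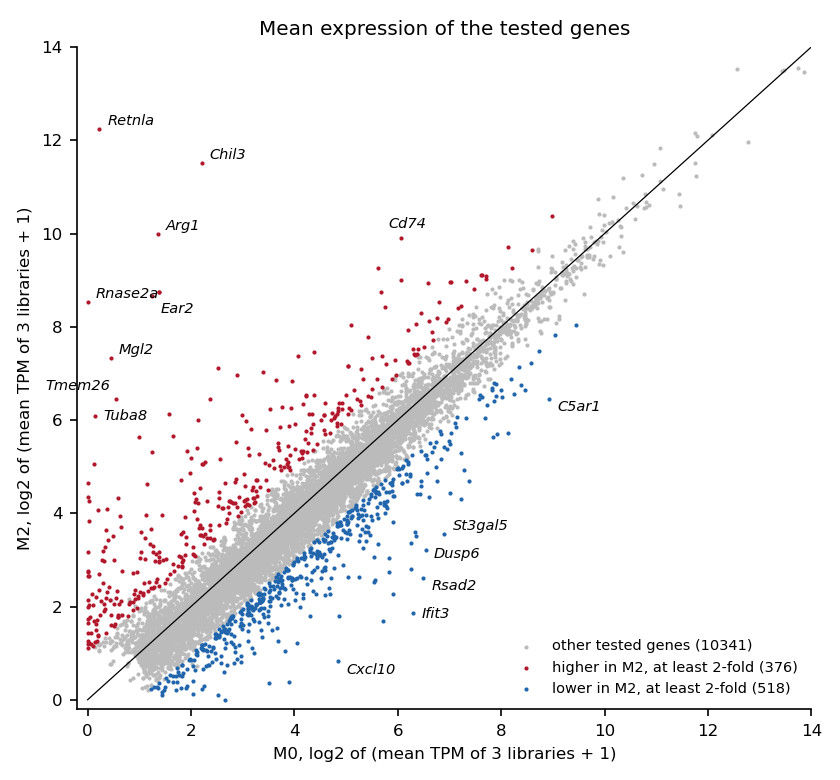
Mean expression of the 11235 tested genes in M0 (horizontal axis) and M2 (vertical axis), as log2 of the mean TPM of 3 libraries plus 1, with the line of equal expression. Red points (376) were higher and blue points (518) lower in M2 by at least 2-fold with an adjusted p under 0.05, and Retnla, Chil3 and Arg1 lie farthest above the line.

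The 10 largest rises in fitted log2 of TPM plus 1, a scale that ranks low genes below their fold in TPM (Cish, outside the 10, rose 363-fold), covered 8 loci. Retnla (transcript NM_020509, mm10 chromosome 16, positions 48842609 to 48844461, 4 exons) had 4 reads over the 3 M0 libraries, so that its ratio of read counts, 29066, had a 95% counting interval from 11352 to 106680. Its fitted log2 fold change was 12.03 (SE 0.11, adjusted p = 1.0e-10). Chil3 (NM_009892, chromosome 3, positions 106147554 to 106167564) rose 804-fold in mean TPM, and Arg1 (NM_007482, chromosome 10, positions 24915207 to 24927470) rose 649-fold. Mgl2, which encodes a galactose-type lectin, rose 437-fold and Tmem26, which encodes a membrane protein, rose 189-fold. Tuba8, an alpha-tubulin gene, had 7 reads over the 3 M0 libraries (0.223, 0.090 and 0 TPM). Its count ratio was 624 (interval 303 to 1554, for counting error only). Genes of the eosinophil-type ribonuclease family made up the rest. Rnase2a (chromosome 14, positions 51255262 to 51256112) had no read in M0 and 370 ± 10.8 TPM in M2, at least 3784-fold higher with a floor of 3 reads over the M0 group. Ear2 (chromosome 14, positions 44102654 to 44103531) rose 290-fold, and the entries Ear3 and Ear12 lie inside the Ear2 span at positions 44102887 to 44103357, so that the 3 entries share reads and are 1 locus.

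The 10 largest falls on the same scale were mostly interferon-induced genes, while Cx3cr1, outside the 10, had a mean TPM 67.6-fold lower in M2. Ifit3 (NM_010501, chromosome 19, positions 34583529 to 34588982, 2 exons) had a log2 fold change of -4.45 (SE 0.12, adjusted p = 2.0e-09). Its neighbours on chromosome 19, Ifit1, Ifit2, Ifit3b and Ifit1bl1, fell with log2 fold changes of -4.02, -3.61, -3.52 and -3.13. Cxcl10, which encodes an interferon-induced chemokine, dropped from 27.6 ± 2.72 to 0.770 ± 0.248 TPM. The antiviral gene Rsad2 and its neighbour Cmpk2 on chromosome 12 fell with log2 fold changes of -3.86 and -3.45. The remaining pair were St3gal5, the GM3 ganglioside synthase gene, at 118 ± 2.62 TPM in M0 and 10.8 ± 0.358 TPM in M2, and Dusp6, which encodes a phosphatase of ERK kinases, at 91.8 ± 0.376 and 8.26 ± 0.604 TPM.

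**Figure D2:**
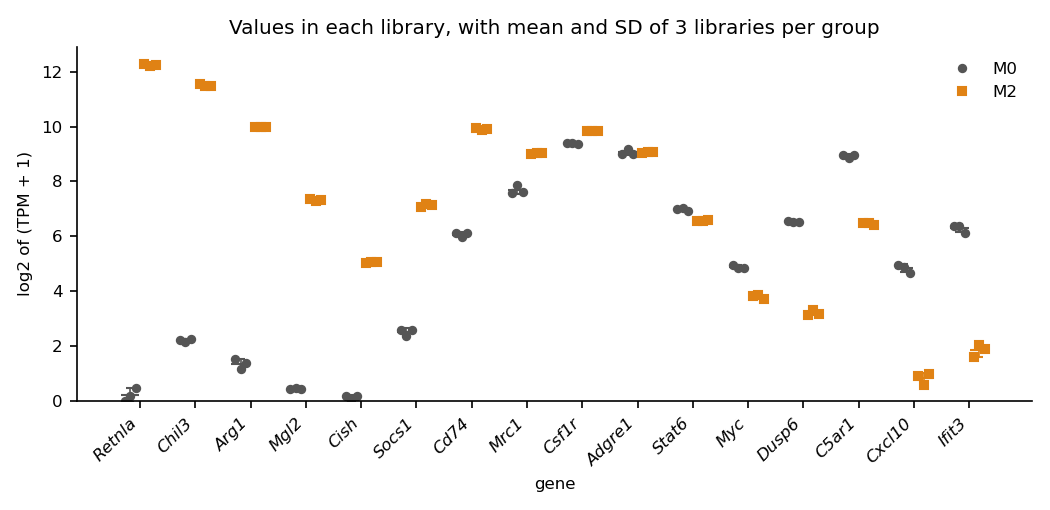
Expression of 16 named genes in each of the 6 libraries as log2 of TPM plus 1 (circles, M0; squares, M2), with the mean and SD of 3 libraries per group. Retnla, Chil3 and Arg1 show the widest gaps upward and Ifit3 and Cxcl10 the widest downward, while Adgre1 differed little and changed sign under median scaling.

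Of 34 tested genes on the IL-4 response and alternative activation list, 32 rose and 2 fell, over all genes tested, adjusted over the list alone and after median scaling (camera adjusted p = 2.4e-28; adjusted p = 0.035 with an estimated correlation). Beyond the genes above, the mannose receptor gene Mrc1 rose from 207 ± 24.6 to 520 ± 7.42 TPM, and the lipid-sensing nuclear receptor gene Pparg from 16.7 ± 1.54 to 35.2 ± 0.602 TPM. The transcription factor genes Egr2 and Irf4 rose with log2 fold changes of 4.08 and 3.02. Myc was among the 2 that fell, from 28.4 ± 1.27 to 12.97 ± 0.831 TPM.

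Among 21 tested JAK-STAT components and feedback genes, 6 rose, 8 fell and 7 did not pass, with the same 6 and 8 adjusted over the list alone and 8 and 6 after median scaling (camera adjusted p = 0.247). The feedback inhibitors rose most: Cish reached 32.4 ± 0.475 TPM from 0.0893 ± 0.0587, Socs1 138 ± 4.29 TPM from 4.71 ± 0.504 and Socs2 19.2 ± 0.286 TPM from 0.503 ± 0.0532. The kinase gene Jak2 rose 3.34-fold. Stat6, which encodes the transcription factor activated by the IL-4 receptor, fell with a log2 fold change of -0.42, and by -0.24 after median scaling. Il4ra, the receptor gene, had a log2 fold change of -0.16 (adjusted p = 0.018) that turned to 0.01 (adjusted p = 0.84) after median scaling. It also missed the threshold without M0 replicate 1 (-0.12) or without M2 replicate 1 (-0.13).

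All 30 type I interferon response genes fell, over all genes tested and adjusted over the list alone, and 29 fell after median scaling (camera adjusted p = 2.0e-11; adjusted p = 0.319 with an estimated correlation). Of 19 tested classical activation genes, 6 rose, 11 fell and 2 did not pass, with the same 6 and 11 adjusted over the list alone and after median scaling (camera adjusted p = 0.572). Tnf fell from 18.6 ± 1.32 to 2.47 ± 0.0998 TPM. Irf1 and Ciita, which encodes the master activator of MHC class II transcription, rose 2.35-fold and 12.9-fold. Nos2, which encodes inducible nitric oxide synthase, stayed below the tested range at 0.0233 ± 0.0101 and 0.0640 ± 0.0288 TPM.

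MHC class II and antigen presentation had 16 tested genes, of which 10 rose, 1 fell and 5 did not pass, with the same 10 and 1 adjusted over the list alone and 12 and 1 after median scaling (camera adjusted p = 5.8e-08; adjusted p = 0.268 with an estimated correlation). Cd74, the invariant chain gene, rose from 65.6 ± 3.90 to 957 ± 23.1 TPM. The class II chain genes H2-Aa, H2-Ab1 and H2-Eb1 rose 10.1-fold, 10.5-fold and 9.85-fold.

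Of 21 tested Toll-like receptors and co-receptors, 4 rose, 10 fell and 7 did not pass, with the same 4 and 10 adjusted over the list alone and 6 and 10 after median scaling (camera adjusted p = 0.496). Tlr2, Tlr13 and the lipopolysaccharide co-receptor gene Cd14 fell with log2 fold changes of -1.94, -1.91 and -1.26, while Tlr8 rose 2.04-fold. Of 14 tested chemokine receptors and motility genes, 4 rose and 10 fell, also adjusted over the list alone and after median scaling (camera adjusted p = 0.252, and 0.0468 with the length trend removed or 0.0381 on the authors' log2-scale values; adjusted p = 0.647 with an estimated correlation). C5ar1, the complement C5a receptor gene, fell from 487 ± 18.0 to 86.6 ± 2.65 TPM, and Cx3cr1 from 4.76 ± 0.266 to 0.0703 ± 0.0319 TPM. Of 25 tested phagocytosis and efferocytosis receptors, 11 rose, 11 fell and 3 did not pass, with the same 11 and 11 adjusted over the list alone and 12 and 10 after median scaling (camera adjusted p = 0.268). The inhibitory Fc receptor gene Fcgr2b rose from 48.4 ± 3.12 to 614 ± 11.9 TPM, whereas the high-affinity activating receptor gene Fcgr1 fell from 128 ± 7.55 to 20.6 ± 1.05 TPM. Clec7a, which encodes the beta-glucan receptor, rose 7.80-fold and the integrin gene Itgb3 rose 8.72-fold.

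All 34 cell cycle genes fell, over all genes tested and adjusted over the list alone, and 33 fell after median scaling (camera adjusted p = 3.0e-10; adjusted p = 0.268 with an estimated correlation). Tpx2, Plk1, Cdt1 and Bub1, which act in spindle assembly, mitotic entry, replication licensing and the spindle checkpoint, had log2 fold changes of -1.57, -1.46, -1.38 and -1.38. Of 36 ribosome biogenesis genes, 35 fell and 1 did not pass, also adjusted over the list alone, and 27 fell with none rising after median scaling (camera adjusted p = 2.3e-06; adjusted p = 0.135 with an estimated correlation). Polr1a, which encodes the largest subunit of RNA polymerase I, and the nucleolar protein gene Nop58 fell with log2 fold changes of -1.16 and -1.03.

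Of 22 glycolysis genes, 3 rose, 16 fell and 3 did not pass, with 3 and 17 adjusted over the list alone and 4 and 14 after median scaling (camera adjusted p = 0.0423; adjusted p = 0.304 with an estimated correlation, and 0.0571 after median scaling, where the call ended). The glycolysis call also ended without M0 replicate 1 (adjusted p = 0.0671) or M0 replicate 3 (adjusted p = 0.0566), with replicate number as a block (0.0558), with at least 50 recovered reads (0.0537) and on the authors' log2-scale values (0.0506). The hexokinase genes Hk1 and Hk2 had log2 fold changes of -1.06 and -0.90. Of 36 oxidative phosphorylation genes, 9 rose, 5 fell and 22 did not pass, with 7 and 2 adjusted over the list alone and 20 and 1 after median scaling (camera adjusted p = 0.0515; adjusted p = 0.553 with an estimated correlation, and 0.00167 after median scaling). With the preset correlation that list also passed without M0 replicate 3 (adjusted p = 0.0111) and without M2 replicate 1, 2 or 3 (adjusted p = 0.0455, 0.0386 and 0.0431), with the length trend removed (0.0248) and on the authors' log2-scale values (0.00306). Uqcrc1 rose 1.20-fold, and Cycs, the cytochrome c gene, had a log2 fold change of -0.48. Of 25 tested fatty acid oxidation and lipid handling genes, 11 rose, 4 fell and 10 did not pass, with the same 11 and 4 adjusted over the list alone and 18 and 3 after median scaling (camera adjusted p = 0.0140; adjusted p = 0.268 with an estimated correlation). Ppargc1b, a coactivator of mitochondrial genes, rose 4.22-fold, whereas the lipoprotein lipase gene Lpl fell from 1008 ± 90.1 to 645 ± 23.0 TPM. Of 24 tested cholesterol synthesis and uptake genes, 3 rose, 15 fell and 6 did not pass, with the same 3 and 15 adjusted over the list alone and 6 and 11 after median scaling (camera adjusted p = 0.307). Dhcr7, a gene of the last steps of the synthesis, rose 2.51-fold and Mvd rose 1.63-fold, while Hsd17b7 fell with a log2 fold change of -0.79. Of 17 tested LXR targets and sterol efflux genes, 6 rose, 5 fell and 6 did not pass, with 6 and 6 adjusted over the list alone and 10 and 4 after median scaling (camera adjusted p = 0.143). The sterol exporter gene Abcg1 rose 3.60-fold while Nr1h3, the gene of LXR alpha, fell from 31.8 ± 1.86 to 13.1 ± 0.629 TPM. Of 19 arginine and polyamine metabolism genes, 7 rose, 10 fell and 2 did not pass, with the same 7 and 10 adjusted over the list alone and 8 and 8 after median scaling (camera adjusted p = 0.307). Besides Arg1, the arginine transporter gene Slc7a2 rose 35.2-fold, Gatm 3.54-fold and the polyamine acetyltransferase gene Sat1 3.14-fold.

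**Figure D3:**
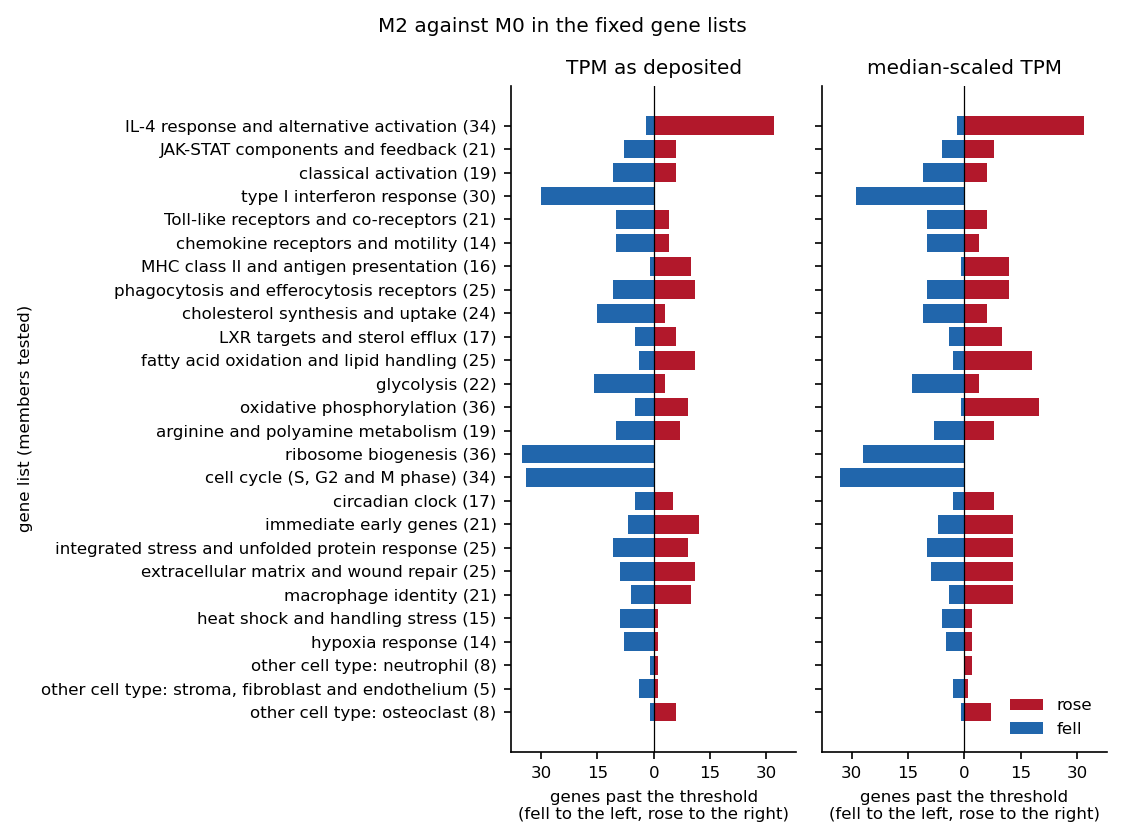
Genes past the threshold in the 26 fixed lists with enough tested members, drawn to the right of 0 where they rose in M2 and to the left where they fell, for TPM as deposited and for median-scaled TPM, with the members tested in brackets. The IL-4, type I interferon, cell cycle and ribosome biogenesis lists keep their side on both scales, while JAK-STAT and integrated stress change their larger side.

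Of 21 tested immediate early genes, 12 rose, 7 fell and 2 did not pass, with the same 12 and 7 adjusted over the list alone and 13 and 7 after median scaling (camera adjusted p = 0.00683; adjusted p = 0.268 with an estimated correlation). The call of that list also ended after median scaling (0.0734), with the length trend removed (0.0968) and on the authors' log2-scale values (0.0506). Ier3 rose 7.83-fold and Egr2 20.8-fold, while Fos and Dusp6 fell with log2 fold changes of -1.97 and -3.33. Of 17 tested circadian clock genes, 5 rose, 5 fell and 7 did not pass, with the same 5 and 5 adjusted over the list alone and 8 and 3 after median scaling (camera adjusted p = 0.101). The clock-linked repressor genes Nfil3 and Bhlhe40 rose 18.6-fold and 4.78-fold, and Bhlhe41 fell from 26.8 ± 1.18 to 10.2 ± 0.492 TPM. Of 25 tested integrated stress and unfolded protein response genes, 9 rose, 11 fell and 5 did not pass, with the same 9 and 11 adjusted over the list alone and 13 and 10 after median scaling (camera adjusted p = 0.375). Pdia4, which encodes a disulfide isomerase of the endoplasmic reticulum, rose from 94.7 ± 3.44 to 490 ± 5.55 TPM, while the amino acid response genes Asns, Slc7a5 and Mthfd2 had log2 fold changes of -1.13, -1.07 and -1.01. Of 15 heat shock and handling stress genes, 1 rose, 9 fell and 5 did not pass, with the same 1 and 9 adjusted over the list alone and 2 and 6 after median scaling (camera adjusted p = 0.0980), and Hmox1, the heme oxygenase gene, fell from 558 ± 15.4 to 288 ± 6.60 TPM. Of 14 tested hypoxia response genes, 1 rose, 8 fell and 5 did not pass, with the same 1 and 8 adjusted over the list alone and 2 and 5 after median scaling (camera adjusted p = 0.375). P4ha2, a collagen prolyl hydroxylase gene, had a log2 fold change of -0.87.

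Of 25 tested extracellular matrix and wound repair genes, 11 rose, 9 fell and 5 did not pass, with the same 11 and 9 adjusted over the list alone and 13 and 9 after median scaling (camera adjusted p = 0.0642, and 0.0488 without M2 replicate 2 or 0.0435 without M2 replicate 3; adjusted p = 0.487 with an estimated correlation). The fibronectin gene Fn1 rose from 9.48 ± 0.921 to 130 ± 1.20 TPM. Plau, the urokinase gene, fell from 278 ± 11.3 to 51.5 ± 2.73 TPM and Tgfbi from 243 ± 9.07 to 50.8 ± 2.55 TPM. Of 21 macrophage identity genes, 10 rose, 6 fell and 5 did not pass, with the same 10 and 6 adjusted over the list alone and 13 and 4 after median scaling (camera adjusted p = 0.0186; adjusted p = 0.372 with an estimated correlation). Csf1r, the M-CSF receptor gene, rose from 674 ± 11.8 to 912 ± 1.97 TPM, and the transcription factor gene Maf fell from 259 ± 6.26 to 89.0 ± 3.79 TPM. Adgre1, the gene of the F4/80 surface marker, stood at 536 ± 43.7 and 534 ± 8.82 TPM, a log2 fold change of -0.00 (adjusted p = 0.98) that became 0.17 (adjusted p = 0.012) after median scaling.

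Among markers of other cell types, none of 11 mast cell and basophil markers was tested, and 1 of 13 T and NK cell markers was, Cd4, which fell with a log2 fold change of -0.26 and missed the threshold after median scaling, without M0 replicate 2 and without each M2 library. Of 2 tested B cell markers, Cd22 rose 2.34-fold and Cd79b fell with a log2 fold change of -0.28, which missed the threshold after median scaling, without M0 replicate 1 and without M2 replicate 2. The counts for these and the next 2 lists were the same adjusted over the list alone. Of 2 tested dendritic cell markers, Ccl22 rose and Bst2 fell, and both also belong to other lists. Of 2 tested erythroid and megakaryocyte markers, both fell, with Pf4 going from 782 ± 77.9 to 414 ± 9.50 TPM. Of 8 tested neutrophil markers, 1 rose, 1 fell and 6 did not pass, also adjusted over the list alone, with 2 and 0 after median scaling (camera adjusted p = 0.375), and Csf3r rose 4.04-fold. Of 5 tested markers of stroma, fibroblast and endothelium, 1 rose and 4 fell, also adjusted over the list alone, with 1 and 3 after median scaling (camera adjusted p = 0.664). Pecam1 rose 25.5-fold while the endothelial receptor gene Kdr fell from 2.78 ± 0.249 to 0.218 ± 0.0370 TPM. Of 8 tested osteoclast markers, 6 rose, 1 fell and 1 did not pass, with the same 6 and 1 adjusted over the list alone and 7 and 1 after median scaling (camera adjusted p = 7.9e-05; adjusted p = 0.268 with an estimated correlation). The tartrate-resistant phosphatase gene Acp5 rose 4.62-fold, and 3 of the risen markers, Dcstamp, Ocstamp and Atp6v0d2, are also on the IL-4 list. The call ended when all genes shared between lists, these among them, were left out (adjusted p = 0.209).

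By limma-trend, 7071 of 11235 tested genes passed an adjusted p of 0.05, of which 1983 rose and 5088 fell, and 894 changed by at least 2-fold, 376 up and 518 down. The median gene had a log2 fold change of -0.15, and after median scaling 6397 genes passed, 3234 up and 3163 down, of which 864 changed by at least 2-fold (493 up, 371 down). In total, 5146 genes passed on both scales, all with the same sign. Without M0 replicate 2, the library that scattered most, 7276 genes passed and 824 changed by at least 2-fold. The authors' deposited table called 6255 genes at the same threshold, 3179 up and 3076 down. Of these, 5801 were among the tested genes, 4848 were shared with the unscaled test and 5687 with the median-scaled test, all with the same sign. Camera with its preset correlation called 10 of the 26 lists, of which the IL-4 list alone passed with an estimated correlation.

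Fold changes were fitted on log2 of TPM plus 1, which understates those of low genes, and values of paralogous or overlapping genes such as the Ifit and Ear entries are uncertain. The p-values measure only the spread between these libraries, since no label says whether they came from separate animals or cultures.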

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

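The tests with median-scaled TPM, voom, the authors' values, length removal and a fold cutoff in the test were chosen after the result was seen. Where a value moved, the cause was not tested unless stated. Rises and falls numbered 3234 and 3163 with median-scaled TPM, 3278 and 3285 with voom on recovered reads, 3318 and 3323 with the authors' log2-scale values, and 3387 and 3254 with the length trend removed, since each of these centres the median gene near 0. Against a fold change of 1.5, 1318 genes passed (523 up, 795 down), and 1189 (657 up, 532 down) on median-scaled TPM. A pseudocount of 5 left 439 genes changed by at least 2-fold, since it shrinks the folds of low genes, against 1228 with 0.1. Totals were 7297 with no filter, 7060 with at least 50 reads and 6916 with replicate number as a block. Expression values, as log2 of TPM plus 1, correlated at 0.980, 0.979 and 0.981 between M0 and M2 libraries of the same number. The check for pairing did not correlate these expression values as such. It gave 0.00495, -0.00487 and -0.0428 for same-number libraries, and -0.0448 to 0.0510 for those with different numbers. No pairing was seen, but a small effect of a shared animal or culture cannot be excluded by these values. Leaving out each library in turn gave 6082 to 7276 genes and 800 to 871 changed by at least 2-fold. Camera called 1 list with an estimated correlation and 9 to 12 under the other alternatives. Fry called 24, but it tests a list against no change and not against other genes, so that its count is not comparable. Over all alternatives, named genes kept direction and side of the threshold in 1969 tests, lost the threshold in 83 and reversed in 12. Lists did so in 313, passed newly in 24 (13 of them under fry), lost it in 20 and reversed in 7. Adgre1 reversed to log2 fold changes of 0.171 (median-scaled TPM, with and without the fold cutoff, and length removed), 0.167 (voom) and 0.160 (authors' values), and ran from -0.0432 without M0 replicate 3 to 0.0639 without M0 replicate 2, also turning positive without M2 replicate 1 (0.0103). Il4ra reversed to 0.0137 (median-scaled, both tests), 0.0117 (voom), 0.00933 (authors' values) and 0.0437 (length removed). The arginine list reversed without shared genes (adjusted p = 0.994), a setting that left out Arg1 and Slc7a2, its largest rises. The integrated stress and stroma lists reversed under fry (0.0468 and 0.000547), where the direction is against no change and not against other genes. With libraries left out, classical activation ran from 0.167 to 0.996, reversing without M0 replicate 1 (0.968), and the stroma list from 0.122 to 0.919, reversing without each M0 library. DESeq2, the edgeR normalizations and filters and glmTreat were not run, a choice made because the deposited unit was TPM, although voom was run on recovered reads.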

Other observations

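The gene lists in this and the next paragraph, the genes named from them, and the tests below of abundant genes, of single libraries and of length trends between libraries, were chosen after the result was seen. The p-values of these lists are therefore descriptive only. The test of the interferon list against transcript length and the comparison with other splits were planned. Of 30 lysosomal hydrolase genes, 20 rose, 5 fell and 5 did not pass (25 and 1 after median scaling), and the list passed camera at an adjusted p of 1.3e-08 (adjusted p = 0.0125 with an estimated correlation). Psap, the saposin precursor gene, rose with a log2 fold change of 0.97, and Ctsz and Naglu with 0.87 and 0.81. Of 25 actin cytoskeleton genes, 2 rose, 19 fell and 4 did not pass (5 and 12 after median scaling; camera adjusted p = 0.00598; adjusted p = 0.0526 with an estimated correlation). Coro1a, the coronin gene, had a log2 fold change of -1.13 and Tmsb4x, the thymosin beta-4 gene, of -0.80, while Zyx rose by 1.69.

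Of 13 tested genes of ERK feedback and growth factor response, 3 rose, 9 fell and 1 did not pass (4 and 9 after median scaling; camera adjusted p = 0.111; adjusted p = 0.209 with an estimated correlation, and 0.0202 after median scaling with the preset one). The feedback inhibitor genes Spry2 and Spred2 and the cyclin gene Ccnd1 fell with log2 fold changes of -2.43, -2.11 and -2.19, alongside Dusp6. Of 6 tested Fc receptor genes, 4 rose and 2 fell on both scales (camera adjusted p = 0.0305; adjusted p = 0.257 with an estimated correlation, and 0.117 after median scaling, where the call ended), with the neonatal receptor gene Fcgrt rising by 0.96. The 4 tested eosinophil-type ribonuclease entries all rose, but they prompted the list and 3 of them are the same locus, so that no list test is given.

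The interferon-response genes fell with a median log2 fold change of -1.64. With each library left out in turn, the median nearest to 0 was -1.60, which argues against a single library as the source. After the trend on transcript length was removed, 30 of the 30 members that fell still fell, which argues against that trend as the whole cause. A lower interferon response in the cells given IL-4 may underlie the fall, but this hypothesis was not itself tested.

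The median gene had a log2 fold change of -0.152 on the TPM scale. The summed TPM of the deposited genes was also lower in M2 (542749 to 543854) than in M0 libraries (548160 to 553186). What that adds to the shift was not tested. With each library left out in turn the shift nearest to 0 was -0.132, which argues against a single library. Leaving out the 50 largest gains and the 50 largest losses in TPM moved it to -0.0867. A larger share taken by a few abundant genes, whose 50 largest gains took 6.58% of TPM while the 50 largest losses changed it by -4.17%, may account for part of the shift. That explanation stayed open, since -0.0867 lay between the bound of -0.05 set for it and the bound of -0.10 set against it.

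Fold changes declined with transcript length, with a Spearman's rho of -0.110 across genes, which are not independent replicates. Without M0 replicate 2 rho was -0.0370, consistent with that library setting most of the trend. Whether libraries differ in length trend whatever their group remained open, since the lowest M0 slope and the highest M2 slope lay 0.0132 apart against a range of 0.0945 within M0. No biological explanation was tested.

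Each of the 10 splits of the 6 libraries into groups of 3 was tested. The real split gave 7071 genes and 894 changed by at least 2-fold, each matched by 1 of the 10 splits, the real one itself, and the highest other split gave 0 and 0 with limma, while 39 to 71 genes had an unadjusted p under 0.05 (7472 in the real split). For gene lists, 3 of the 10 splits gave at least the 10 lists of the real split, and the highest other gave 11. Every other split puts M0 and M2 libraries together in each group. Part of the difference between M0 and M2 thus stays between its groups, and the rest adds to the spread within them. The other splits therefore cannot show how many genes or lists are called where nothing differs. With 10 splits a share under 0.05 cannot be reached.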
